A study of Rattus norvegicus with 94 samples.

How the data were processed

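RNA from livers of male rats was measured on Affymetrix rat genome arrays. Per the labels, total RNA was isolated with RNA STAT-60, 10 µg went into each labelling, and the deposited intensities are MAS 5.0 signals scaled by the authors to a target of 1500 on the linear scale. A series without its paper was used, and no step beyond what the labels state is assumed. The 94 columns were assigned to samples by their names, and all 23 scanner files that name a condition matched the labels. Clofibrate was given in 0.9% saline and VPA and DEHP in distilled water, and each compound had its own vehicle animals. Arrays of 1 animal each (26 for clofibrate, 26 for DEHP, 24 for VPA) were used for all tests, and the 18 pooled arrays only for the comparison of pooling. No pair of arrays held mostly identical values. Signals were deposited to 1 decimal for 22 arrays, 4 of them individual.

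Of 8799 probe sets 7018 carried 1 gene symbol in the platform table, 308 several and 1473 none, for 4737 symbols. Of the 7018, 6994 had a gene identifier in the reference table, and 0 symbols needed an update. Probe sets of related genes, such as the Cyp4a, Cyp2b, Gst and Ugt2b families, may detect more than 1 transcript, so that a symbol there stands for a family.

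Signals below 150 were set to 150 and log2 was taken. Control probe sets were left out, and probe sets with a mean signal of at least 500 in 1 or more groups of a fit were kept, 3616 for clofibrate, 4092 for DEHP, 4269 for VPA and 4503 for the fit of all 18 groups. Group means were fitted per compound with limma 3.58.1 (lmFit, eBayes with an intensity trend) in R 4.3.3, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Treated groups at 48 and 168 h were compared with the vehicle group of that time, and those at 4 and 24 h, which had none, with the equal-weight mean of both vehicle groups of the compound. These early comparisons share vehicle arrays with the later ones of the same compound, so calls within a compound are not compared by overlap. Differences between times were tested as interactions within a compound and differences between compounds in the fit of all 76 individual arrays. Adjusted p values measure spread between these arrays. A fold or difference is called at least its value where arrays lay at the floor on its lower side alone, and no size is given where they lay on its higher side. Standard errors of such genes are set in part by the floor, and their place in the order of sizes is not known.

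A set of 25 gene lists was fixed before the data were examined. Lists were tested with limma camera at a preset correlation of 0.01 on 1 probe set per gene, and with camera using an estimated correlation and with fry beside it, where 3 or more members were measured, with adjustment over all 296 tests of the 12 treated comparisons. Of the 119 calls 97 were also called by fry in the same direction. An error in the matching of older gene names, which had given 2 list members a wrong gene, was corrected after values had been seen. Prefix matches put some genes into lists that their name does not describe, such as Atp5if1, an ATPase inhibitor, among oxidative phosphorylation subunits. The choice of which list calls to print was also made after values were seen.

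Genes were named by a rule fixed beforehand. It took the 10 largest rises and falls among probe sets with 1 symbol, adjusted p under 0.05, a mean signal of at least 1000 in the higher group and no overlap between arms. It added up to 4 members of smallest adjusted p per list, and per direction 5 genes for response differences and 3 probe sets for pooling. Of a gene's passing probe sets that of highest mean signal was shown, and others may be uncalled.

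For pooling, the SD over probe sets of the pooled log2 signal minus the mean of the individual arrays was set against the same SD for each individual array around the mean of the others, scaled for the number of arrays, with an exact sign-flip permutation test over the 18 groups.

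Scripts were tested on simulated data with about 200 probe sets changed by 1.5-, 2- or 4-fold. At 2-fold 70.1 to 90.8% were recovered and at 1.5-fold 28.4 to 68.2%, and 3.63 to 9.09% of calls were false. Real arrays may give other rates. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and jsonlite 2.0.0. Alternatives covered scaling, floor, filter, variance prior, arrays in the fit, blocks for replicate and scan day, single arrays left out and other vehicle groups. The 3'/5' ratio as a covariate, array weights and the fit without the 4 arrays given to 1 decimal were chosen after seeing the data.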

Results

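The livers of male Sprague-Dawley rats were profiled after a single dose of 1 of 3 compounds, and the question was which transcripts each compound changed, and when. Clofibrate, a lipid-lowering fibrate drug, was given at 1000 mg/kg, valproic acid as its sodium salt (VPA), an anticonvulsant that is itself a branched fatty acid, at 2000 mg/kg, and di(2-ethylhexyl) phthalate (DEHP), a plasticizer, at 20 g/kg. Livers were taken 4, 24, 48 or 168 h after the dose, and each compound had its own vehicle groups at 48 and 168 h. The 94 arrays comprised 76 arrays of 1 animal each, in 18 groups, and 18 arrays of pooled RNA, 1 per group. There were 3 animals per group at 4 and 24 h and 5 in the remaining groups, except 4 in the VPA-treated groups at 48 and 168 h. Each array held 8799 probe sets, of which 59 were controls. The trimmed mean signal lay between 1499.9 and 1500.8 on every array, the median signal between 211.6 and 415.2, and 33.2 to 45.9% of probe sets per array reached a signal of 500. The number of arrays limits the precision of every value. Signals under 150 were set to that floor, and a fold or difference is given as at least its value where arrays of the lower side lay there.

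RNA measures differed between the compounds' sets of arrays. The log2 ratio of 3' to 5' signal, averaged over the control probe sets for Gapdh and beta-actin, was 1.38 ± 0.65 (SD, n = 26) on the individual arrays of the clofibrate set, 0.33 ± 0.14 (n = 26) in the DEHP set and 0.34 ± 0.14 (n = 24) in the VPA set. Within the clofibrate set it was 1.26 ± 0.70 in the 48 h treated group and 1.77 ± 0.80 in the 48 h vehicle group (n = 5 each). The highest ratios of that set, 2.40 to 2.74, came from 4 arrays whose signals were deposited to 1 decimal, namely clofibrate 24 h replicate 3, clofibrate 48 h replicate 5 and vehicle 48 h replicates 4 and 5.

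**Figure D1:**
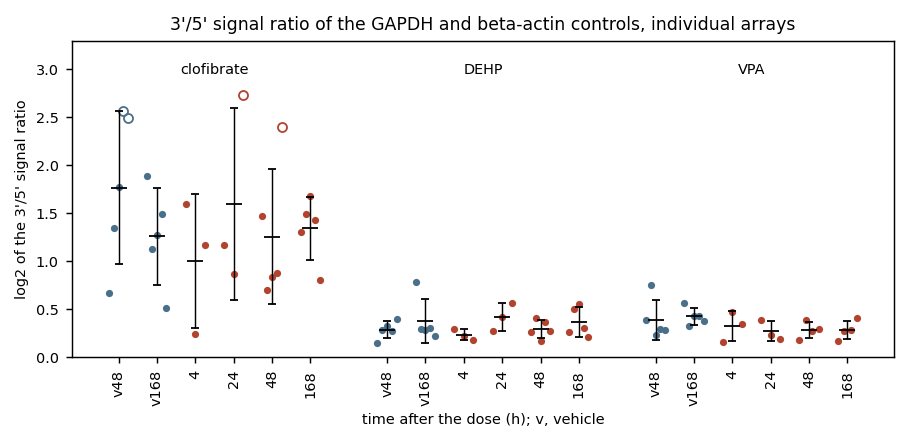
Log2 ratio of 3' to 5' signal (mean of the Gapdh and beta-actin controls) on each individual array, by compound and time after the dose in h, with vehicle groups marked v. Points are arrays, bars are group means ± 1 SD, and open circles are the 4 arrays given to 1 decimal, which lie between 2.40 and 2.74 while DEHP and VPA arrays reach at most 0.789.

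**Figure D2:**
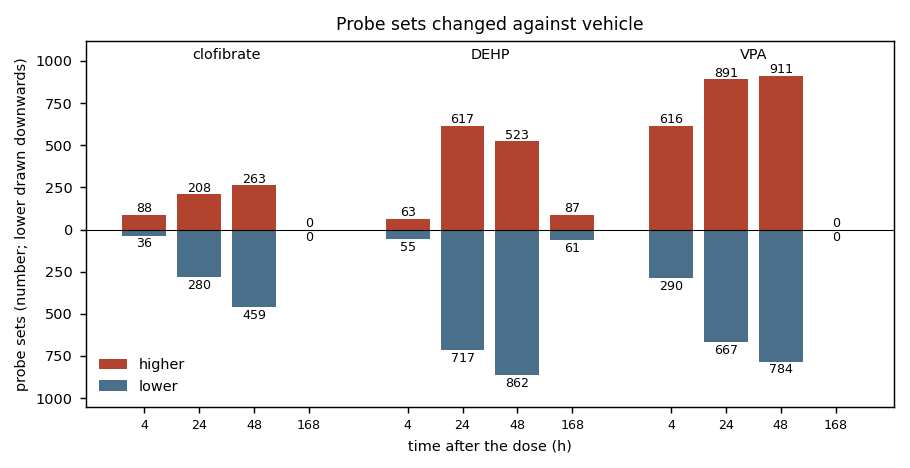
Number of probe sets higher (upward bars) and lower (downward bars) than in vehicle at an adjusted p under 0.05, by compound and time after the dose in h. At 48 h 722 were called for clofibrate, 1385 for DEHP and 1695 for VPA, and at 168 h only DEHP had calls, 87 higher and 61 lower.

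Here and below, largest changes are those among probe sets with a mean signal of at least 1000 in the higher group and no overlap between arms, so that list members outside that rule can be larger. At 4 h after clofibrate the largest rises over vehicle were Acaa1b (9.68-fold, log2 change 3.28 ± 0.22, adjusted p = 4.08e-10), which encodes a peroxisomal thiolase, Pdk4 (at least 9.66-fold), a kinase that inhibits pyruvate dehydrogenase, Pex11a (8.91-fold), which acts in peroxisome division, and Sds (8.08-fold). Next came Ehhadh (8.07-fold), the peroxisomal bifunctional enzyme, Hacl1 (8.03-fold), Cyp4a1 (7.77-fold), a fatty acid omega-hydroxylase, Acot1 (at least 6.85-fold), an acyl-CoA thioesterase, and Eci1 (6.05-fold). Largest among the falls were Tsc22d1 (5.40-fold), a transcriptional regulator, Tuba4a (4.98-fold) and Dusp6 (3.84-fold), a phosphatase of MAP kinases. Next came Cited2 (3.14-fold), Fkbp4 (2.38-fold), Kank2 (2.20-fold) and Dhcr7 (2.08-fold). These genes had standard errors of the log2 changes of at most 0.60 and adjusted p of at most 0.00341. Acot2, Msmo1, Sdc1 and Mvd, also among the 20 largest changes, lost their call without 1 or more of clofibrate 4 h replicates 1 to 3, with highest adjusted p values of 0.204, 0.201, 0.0844 and 0.116.

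Counts of list members by list alone, adjusted over the list's members only (those in the list's direction first), are given where they differ. In the list of peroxisomal beta-oxidation and peroxisome genes 4 of 13 rose (6 by list alone, adjusted p = 2.68e-06 and 0.00147 with an estimated correlation). In the list of mitochondrial beta-oxidation and ketogenesis, 6 of 19 rose (adjusted p = 6.07e-10 and 0.004 with an estimated correlation). Among them were Cpt1a (4.47-fold), the carnitine palmitoyltransferase of the outer membrane, and Cpt2 (3.13-fold). In the list of fatty acid omega-hydroxylation, binding and activation, 3 of 18 rose (4 by list alone, adjusted p = 0.000187 and 0.0108 with an estimated correlation). In the circadian list 3 of 5 rose and 0 fell (3 and 1 by list alone, adjusted p = 0.000117 and 0.0073 with an estimated correlation). They were Nr1d1 (4.04-fold, log2 change 2.02 ± 0.22, adjusted p = 1.62e-06), Dbp (at least 5.01-fold) and Nr1d2 (at least 3.52-fold). Leukocyte and Kupffer cell markers lay lower with 0 of 15 called (adjusted p = 0.0169, adjusted p = 0.285 with an estimated correlation).

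Of 3616 probe sets 88 were higher and 36 lower (limma, adjusted p under 0.05, n = 3 against 10), and 133 with scan day as a block. Vehicle animals were killed at 48 and 168 h, so time since dosing differed. Labels give no time of day, so circadian changes may stem from it. The count was 79 against 168 h vehicle alone and 735 against the mean of all 6 vehicle groups, which adds other array sets. It was 78 without clofibrate 4 h replicate 2 or 3 and 204 with the 3'/5' ratio as covariate. It was 122 without the 4 arrays given to 1 decimal, 295 fitting all 18 groups and 646 with array weights.

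At 24 h after clofibrate the largest rise was Acot1 (at least 337-fold, adjusted p = 5.66e-15, 10 of 10 vehicle arrays at the floor). Other large rises were Acaa1b (42.5-fold), Ehhadh (23.9-fold), Pex11a (20.8-fold) and Eci1 (16.6-fold), a mitochondrial enoyl-CoA isomerase. Next came Ech1 (16.5-fold), Hdc (at least 14.7-fold), histidine decarboxylase, Acot2 (at least 12.6-fold), Aldh1a1 (11.4-fold), a retinaldehyde dehydrogenase, and Cyp4a1 (11.0-fold). Falls were led by Tsc22d1 (6.58-fold), Fabp5 (5.23-fold), Pklr (4.74-fold), the liver pyruvate kinase, and Bhmt (4.71-fold), which remethylates homocysteine. Next came Hyou1 (4.21-fold), a chaperone of the endoplasmic reticulum, C1s (3.93-fold), Slc2a2 (3.71-fold), the liver glucose transporter, Slc37a4 (3.67-fold) and Cited2 (3.49-fold). Standard errors of the log2 changes were at most 0.70 and adjusted p at most 0.000804 for these genes (n = 3 against 10). Car3, also among the 10 largest falls, lost its call without some single arrays, with a highest adjusted p of 0.159 without clofibrate 24 h replicate 1.

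Among peroxisomal genes 8 of 13 rose and 2 fell (adjusted p = 3.58e-09 and 0.000121 with an estimated correlation). Among mitochondrial beta-oxidation genes 14 of 19 rose (adjusted p = 3.35e-19 and 0.000107 with an estimated correlation). The rises included Hadhb (2.85-fold), Slc25a20 (5.19-fold), Acaa2 (2.89-fold) and Cpt2 (3.58-fold). In the omega-hydroxylation, binding and activation list 8 of 18 rose and 2 fell (9 and 4 by list alone, adjusted p = 0.000681 and 0.0195 with an estimated correlation). In the list of the unfolded protein response 9 of 17 fell and 0 rose (10 and 1 by list alone, adjusted p = 0.000175, adjusted p = 0.0865 with an estimated correlation). The falls included Hspa5 (2.50-fold), Pdia4 (3.21-fold) and Calr (2.12-fold). In the heat shock list 4 of 11 rose (adjusted p = 0.000861, adjusted p = 0.104 with an estimated correlation), with rises of the mitochondrial chaperonins Hspe1 (2.42-fold) and Hspd1 (1.70-fold). In the acute phase list 9 of 23 fell (10 by list alone, adjusted p = 6.79e-05, adjusted p = 0.06 with an estimated correlation). Lower members included Kng2 (1.84-fold), Serpina3n (1.93-fold) and Fgg (1.62-fold). In the proteasome list 7 of 26 rose and 0 fell (15 and 1 by list alone, adjusted p = 8.29e-06, adjusted p = 0.0812 with an estimated correlation). In the cell cycle list 4 of 15 rose (7 by list alone, adjusted p = 0.0012, adjusted p = 0.195 with an estimated correlation). Among them was Mcm6 (at least 3.94-fold), a subunit of the replicative helicase. In the cholesterol list 4 of 14 fell (6 by list alone, adjusted p = 0.00163, adjusted p = 0.207 with an estimated correlation). Of inducible phase I enzymes 4 of 15 rose and 1 fell (adjusted p = 0.0133, adjusted p = 0.294 with an estimated correlation). The rises included Cyp2b2 (6.37-fold), a phenobarbital-inducible P450. Leukocyte and Kupffer cell markers fell in 3 of 15 members (adjusted p = 0.00936, adjusted p = 0.236 with an estimated correlation), with C1qc (1.67-fold) lower.

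Across the array 208 probe sets were higher and 280 lower (limma, n = 3 against 10), and 460 with scan day as a block. Centring each array on its median gave 234 higher and 196 lower. The vehicles were not time-matched. The count was 2284 against all 6 vehicle groups, which adds other array sets. It was 942 with the 3'/5' ratio as a covariate, 439 without the 4 arrays given to 1 decimal, 873 in a fit of all 18 groups and 911 with array weights.

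At 48 h, against the vehicle group of the same time, the largest clofibrate rises were Acot1 (at least 307-fold, adjusted p = 1.88e-15, 5 of 5 vehicle arrays at the floor), Acaa1b (45.5-fold), Ehhadh (37.9-fold), Eci1 (22.5-fold) and Acot2 (at least 19.5-fold). Next came Hdc (at least 19.0-fold), Fabp3 (at least 16.6-fold), a fatty acid binding protein typical of muscle, Ech1 (14.6-fold), Pex11a (14.0-fold) and Aqp3 (at least 10.4-fold), an aquaglyceroporin. Outside those 10 was Cyp4a1 (9.02-fold, log2 change 3.17 ± 0.17, adjusted p = 3.47e-13). The falls of largest size were Dusp1 (at least 9.02-fold), a phosphatase of MAP kinases, Lox (at least 7.84-fold), lysyl oxidase, Dio1 (7.80-fold), the type 1 deiodinase, Fmo1 (6.70-fold), a flavin-containing monooxygenase, and Apoa4 (6.15-fold), an apolipoprotein. Next came Tsc22d1 (5.77-fold), Mpv17l (at least 5.73-fold), Hsd11b1 (5.24-fold), Cyp1a2 (4.46-fold) and Pklr (3.93-fold). These genes (n = 5 against 5) had standard errors of the log2 changes of at most 0.84 and adjusted p of at most 0.0149.

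Of the peroxisomal list 9 of 13 rose and 1 fell (adjusted p = 5.84e-10 and 0.000107 with an estimated correlation). Of the mitochondrial beta-oxidation list 15 of 19 rose (16 by list alone, adjusted p = 5.52e-21 and 0.000107 with an estimated correlation), including Hadhb (3.13-fold), Acaa2 (3.43-fold) and Acadvl (2.40-fold). Of the omega-hydroxylation, binding and activation list 7 of 18 rose and 3 fell (8 and 3 by list alone, adjusted p = 0.000102 and 0.00856 with an estimated correlation). The rises included Slc27a2 (3.81-fold), a fatty acid transporter and acyl-CoA synthetase. Of acute phase proteins, which the liver secretes, 12 of 23 fell (13 by list alone, adjusted p = 3.88e-06 and 0.0233 with an estimated correlation). Among them were Kng2 (2.18-fold), C3 (1.88-fold), Apcs (1.98-fold) and Itih3 (1.80-fold). In the proteasome list 9 of 26 rose (10 by list alone, adjusted p = 5.78e-06, adjusted p = 0.0755 with an estimated correlation). Among inducible phase I enzymes 6 of 15 rose and 2 fell (adjusted p = 0.00107, adjusted p = 0.177 with an estimated correlation). Cyp2b15 (2.89-fold) and Alas1 (3.02-fold) were higher and Cyp1a2 lower. In the cholesterol list 6 of 14 fell (9 by list alone, adjusted p = 0.0185, adjusted p = 0.357 with an estimated correlation). Lower members included Dhcr7 (1.95-fold), Msmo1 (1.92-fold) and Mvd (1.80-fold). In the oxidative phosphorylation list 6 of 50 rose and 1 fell (adjusted p = 0.00282, adjusted p = 0.28 with an estimated correlation). The rises included Ndufa3 (2.49-fold).

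Of leukocyte and Kupffer cell markers 5 of 15 fell (6 by list alone, adjusted p = 0.0415, adjusted p = 0.354 with an estimated correlation). Among them was C1qc (1.58-fold). Of stellate cell, fibroblast and matrix markers 4 of 10 fell (6 by list alone, adjusted p = 0.0185, adjusted p = 0.0895 with an estimated correlation). Among them were Lox and Bgn (1.86-fold). Of erythroid and blood markers 2 of 5 fell (adjusted p = 0.0355, adjusted p = 0.287 with an estimated correlation). Among them was Hbb (1.73-fold).

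In all 263 of 3616 probe sets were higher and 459 lower (limma, n = 5 against 5), and 613 were called with scan day as a block. The treated arrays had the lower mean 3'/5' ratio, 1.26 against 1.77, and the count was 1046 with that ratio as a covariate, 525 without the 4 arrays given to 1 decimal, 1232 in a fit of all 18 groups, 1379 with array weights and 479 with only the groups compared.

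At 168 h no probe set was called against vehicle after clofibrate (limma, n = 5 against 5), and 78 of 3616 had an unadjusted p under 0.05, with 1 call without clofibrate 168 h replicate 5 and 1 with array weights. No member was called in the lists of cholesterol synthesis, immediate early and stress response, heat shock proteins, and gluconeogenesis, amino acid catabolism and urea cycle, adjusted over the list alone or over all genes. As lists, the first 3 tended lower (adjusted p = 0.00223, 0.0026 and 0.0439) and the last higher (adjusted p = 0.00849), and none kept its call (adjusted p = 0.221, adjusted p = 0.185, adjusted p = 0.287 and adjusted p = 0.285 with an estimated correlation).

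**Figure D3:**
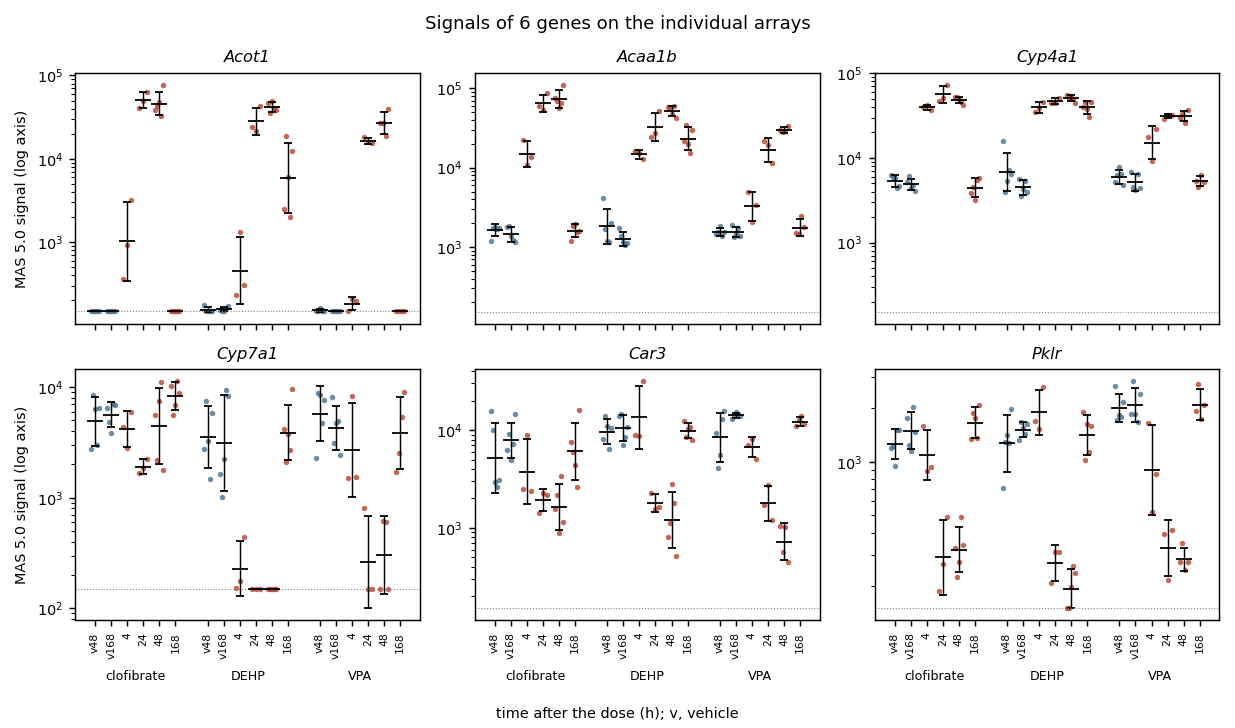
Signal (log scale) of 6 genes on each individual array by compound and time after the dose in h, vehicle groups (v) in blue and treated groups in red. Points are arrays, with values under 150 drawn at 150 (dotted line), and bars are geometric means ± 1 SD on the log2 scale. Acot1 in vehicle arrays is at most 175.4 and in DEHP arrays at 168 h lies between 2009 and 18576.

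At 4 h after DEHP the largest rises by that rule were Pdk4 (10.2-fold, log2 change 3.35 ± 0.40, adjusted p = 9.39e-06), Acaa1b (9.72-fold), Acot2 (at least 9.28-fold) and Cyp4a1 (7.16-fold). Next came Plin2 (2.82-fold), a lipid droplet protein, Cpt2 (2.76-fold), Ehhadh (2.73-fold) and Pdp2 (2.72-fold), a pyruvate dehydrogenase phosphatase. The largest fall was Cyp7a1 (14.7-fold, log2 change -3.88 ± 0.54, adjusted p = 8.05e-05), the rate-limiting enzyme of bile acid synthesis, followed by Cited2 (3.47-fold), Gclc (2.10-fold) and Fkbp4 (2.09-fold). For these 12 genes (n = 3 against 10) standard errors of the log2 changes were at most 0.54 and adjusted p at most 0.00177. Of the 20 genes with the largest changes, Klf10, Me1, Chka, Pnrc1, Enpp3, Aopep, Gucy1b2 and Cldn3 lost their call when 1 of some single arrays was left out, mostly DEHP 4 h replicate 1, 2 or 3, with highest adjusted p values of 0.123, 0.0851, 0.26, 0.115, 0.211, 0.293, 0.0964 and 0.183.

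In the peroxisomal list 5 of 13 rose (6 by list alone, adjusted p = 1.44e-06, adjusted p = 0.0865 with an estimated correlation). Among them was Ech1 (3.21-fold). In the mitochondrial list 4 of 20 rose (6 by list alone, adjusted p = 6.68e-06, adjusted p = 0.195 with an estimated correlation). Leukocyte and Kupffer cell markers lay lower with 0 of 15 called (adjusted p = 0.0405, adjusted p = 0.514 with an estimated correlation). Nr1d1 (2.38-fold), a clock gene, rose as with clofibrate, and time of day is open.

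There were 63 higher and 55 lower probe sets of 4092 (limma, n = 3 against 10), 63 and 66 with quantile normalization, and 59 in all with scan day as a block. The vehicles were not time-matched, with 72 calls against the 168 h vehicle group alone and 386 against the mean of all 6 vehicle groups. The count was 54 without DEHP 4 h replicate 2 and 57 without replicate 3.

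At 24 h the largest DEHP rises were Acot1 (at least 180.3-fold, adjusted p = 2.94e-11, 6 of 10 vehicle arrays at the floor), Acot2 (at least 40.7-fold), Acaa1b (21.4-fold), Trib3 (at least 12.4-fold) and Ech1 (10.4-fold). Next came Ehhadh (10.2-fold), Slc3a2 (9.20-fold), a subunit of amino acid transporters, Cyp2b2 (9.16-fold), Cyp4a1 (8.42-fold) and Ddit3 (at least 8.35-fold), a transcription factor of the integrated stress response. Lower by the most were Cyp7a1 (at least 22.3-fold, adjusted p = 6.34e-07, 3 of 3 treated arrays at the floor), Fmo1 (at least 9.26-fold), Tsc22d1 (8.27-fold), Lox (at least 8.14-fold) and Ptgr1 (at least 7.12-fold). Next came Cited2 (6.59-fold), Socs2 (at least 6.22-fold), a suppressor of cytokine signalling, Car3 (5.63-fold), a carbonic anhydrase, Pklr (5.11-fold) and C1s (4.84-fold). The 20 genes (n = 3 against 10) had standard errors of the log2 changes up to 0.57 and adjusted p of at most 0.000401.

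Of proteasome subunits 19 of 26 rose and 2 fell (20 and 2 by list alone, adjusted p = 4.03e-13 and 0.0124 with an estimated correlation). Among them were Psma7 (2.57-fold), Psmc5 (2.41-fold) and Psmb3 (2.42-fold). Of ribosomal proteins 28 of 41 rose (adjusted p = 7.29e-10, adjusted p = 0.192 with an estimated correlation). Of targets of the unfolded protein response and Atf4 10 of 17 rose and 1 fell (10 and 2 by list alone, adjusted p = 0.00292, adjusted p = 0.307 with an estimated correlation), with Trib3, Slc3a2 and Ddit3 among the rises and Cth (2.72-fold) the fall. Of mitochondrial beta-oxidation genes 15 of 20 rose and 2 fell (adjusted p = 1.30e-09, adjusted p = 0.111 with an estimated correlation). The rises included Cpt2 (3.67-fold) and Eci1 (7.56-fold). Of peroxisomal genes 8 of 13 rose and 3 fell (adjusted p = 0.000177, adjusted p = 0.163 with an estimated correlation). Of heat shock proteins 6 of 12 rose (adjusted p = 0.00178, adjusted p = 0.157 with an estimated correlation). Of inducible phase I enzymes 6 of 15 rose and 3 fell (7 and 3 by list alone, adjusted p = 0.0477, adjusted p = 0.285 with an estimated correlation). Cyp2b15 (3.03-fold) was higher and Cyp1a2 (3.61-fold) lower.

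Of male-predominant liver genes 7 of 11 fell (adjusted p = 0.000706, adjusted p = 0.173 with an estimated correlation). Among them were Car3, Cyp2a2 (1.57-fold), Cyp2c11 (1.90-fold) and Igf1 (1.92-fold). Of acute phase proteins 14 of 23 fell (adjusted p = 3.70e-05, adjusted p = 0.185 with an estimated correlation). Lower members included Cp (2.20-fold), C9 (2.22-fold) and Serpina3n (1.86-fold). Of leukocyte and Kupffer cell markers 7 of 15 fell (8 by list alone, adjusted p = 0.0133, adjusted p = 0.396 with an estimated correlation). Among them was Clec4f (1.92-fold). Of stellate cell, fibroblast and matrix markers 8 of 14 fell (adjusted p = 0.00333, adjusted p = 0.177 with an estimated correlation). Among them were Lox, Fn1 (1.93-fold) and Col1a2 (1.79-fold). Across 4092 probe sets 617 were higher and 717 lower (limma, not time-matched), and 1328 were called with scan day as a block. The majority turned with quantile normalization, 667 higher and 635 lower, and with median centring, 669 and 635.

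At 48 h, against time-matched vehicle, the largest DEHP rises were Acot1 (at least 269.8-fold, adjusted p = 2.13e-12, 4 of 5 vehicle arrays at the floor), Acot2 (at least 33.8-fold), Acaa1b (29.0-fold), Gsta3 (12.8-fold), a glutathione transferase, and Ehhadh (12.3-fold). Next came Aldh1a1 (12.3-fold), Ech1 (11.4-fold), Pdk4 (10.9-fold), Cyp2b2 (9.81-fold) and Pex11a (9.53-fold). Down by the most were Cyp7a1 (at least 23.8-fold, adjusted p = 1.93e-07, 5 of 5 treated arrays at the floor), Fmo1 (16.0-fold), Lox (at least 8.99-fold), Car3 (8.05-fold) and Dio1 (8.03-fold). Next came Tsc22d1 (7.77-fold), Pklr (at least 6.56-fold), Hsd11b1 (6.13-fold), Slc2a2 (5.64-fold) and Avpr1a (4.92-fold), a vasopressin receptor. Among the 20 genes standard errors of the log2 changes were at most 0.52 and adjusted p at most 5.91e-06.

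Of proteasome subunits 18 of 26 rose and 2 fell (19 and 2 by list alone, adjusted p = 1.74e-12 and 0.0148 with an estimated correlation). Of ribosomal proteins 20 of 41 rose (25 by list alone, adjusted p = 8.99e-09, adjusted p = 0.22 with an estimated correlation). Of heat shock proteins 7 of 12 rose (8 by list alone, adjusted p = 0.000159, adjusted p = 0.0865 with an estimated correlation). Of mitochondrial beta-oxidation genes 16 of 20 rose (adjusted p = 6.33e-14, adjusted p = 0.0553 with an estimated correlation). Among them was Acaa2 (2.55-fold). Of peroxisomal genes 8 of 13 rose and 3 fell (adjusted p = 2.68e-06, adjusted p = 0.0895 with an estimated correlation). Of omega-hydroxylation, binding and activation genes 10 of 19 rose and 4 fell (11 and 4 by list alone, adjusted p = 0.000499, adjusted p = 0.111 with an estimated correlation). The rises included Cd36 (at least 4.86-fold), a fatty acid translocase. Of inducible phase I enzymes 8 of 15 rose and 2 fell (8 and 3 by list alone, adjusted p = 0.00061, adjusted p = 0.0865 with an estimated correlation). Higher members included Por (2.52-fold), the P450 reductase. Of genes of glutathione, NRF2 targets and conjugation 9 of 24 rose and 4 fell (adjusted p = 0.00909, adjusted p = 0.118 with an estimated correlation). The rises included Gsta3, Ephx1 (2.07-fold) and Gsr (1.44-fold). In the oxidative phosphorylation list 7 of 50 rose and 3 fell (5 and 1 by list alone, adjusted p = 0.00849, adjusted p = 0.518 with an estimated correlation).

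Among male-predominant liver genes 6 of 11 fell (adjusted p = 0.0101, adjusted p = 0.287 with an estimated correlation), Hsd3b5 (2.32-fold) being 1 of them. Of acute phase proteins 14 of 23 fell and 1 rose (adjusted p = 0.00416, adjusted p = 0.372 with an estimated correlation). Lower members included Serpina3n (2.11-fold) and Serpina3m (2.29-fold). Of leukocyte and Kupffer cell markers 9 of 15 fell (adjusted p = 0.0203, adjusted p = 0.439 with an estimated correlation). Among them were Aif1 (at least 3.66-fold) and C1qb (1.95-fold). Of stellate cell, fibroblast and matrix markers 11 of 14 fell (adjusted p = 0.000352, adjusted p = 0.111 with an estimated correlation). Among them were Col3a1 (2.76-fold) and Fn1 (2.20-fold). In all 523 of 4092 probe sets were higher and 862 lower (limma, n = 5 against 5), and 1173 were called with scan day as a block. Median centring of each array gave 684 higher and 611 lower.

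At 168 h after DEHP the largest rises over time-matched vehicle were Acot1 (at least 37.6-fold, adjusted p = 2.18e-08, 2 of 5 vehicle arrays at the floor), Acaa1b (18.4-fold, log2 change 4.20 ± 0.28, adjusted p = 1.32e-10), Acot2 (at least 15.7-fold), Cyp4a1 (8.80-fold) and Aldh1a1 (6.14-fold). Next came Ech1 (5.85-fold), Ehhadh (5.70-fold), Pex11a (5.22-fold), Eci1 (5.05-fold) and Me1 (4.99-fold), the cytosolic malic enzyme. On the lower side stood Apoa4 (5.24-fold, log2 change -2.39 ± 0.16, adjusted p = 1.32e-10), Dio1 (2.05-fold), Papss2 (1.97-fold), Ntf3 (1.74-fold), Clec4f (1.69-fold), a Kupffer cell lectin, and C1s (1.67-fold). For these 16 genes (n = 5 against 5) standard errors of the log2 changes were at most 0.49 and adjusted p at most 0.0134. Cyp3a9, Idi1, Ces1e and Olr59, also among the 10 largest falls, lost their call without some single arrays of either group, with highest adjusted p values of 0.0579, 0.0857, 0.0646 and 0.117.

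Of the peroxisomal list 7 of 13 rose (8 by list alone, adjusted p = 4.03e-13 and 0.00906 with an estimated correlation). Of the mitochondrial beta-oxidation list 10 of 20 rose and 0 fell (15 and 1 by list alone, adjusted p = 1.26e-20 and 0.0124 with an estimated correlation). Among them were Decr1 (3.46-fold) and Cpt2 (2.60-fold). Of the omega-hydroxylation, binding and activation list 8 of 19 rose and 0 fell (10 and 2 by list alone, adjusted p = 6.07e-10 and 0.00695 with an estimated correlation). Among them was Dbi (1.53-fold), the acyl-CoA binding protein. In the leukocyte and Kupffer cell list 2 of 15 fell (4 by list alone, adjusted p = 5.72e-05, adjusted p = 0.164 with an estimated correlation), Clec4f being 1 of them. The counts were 87 higher and 61 lower of 4092 probe sets (limma, n = 5 against 5), and 135 with scan day as a block.

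At 4 h after VPA the largest rises by that rule were Pdk4 (10.7-fold, log2 change 3.43 ± 0.33, adjusted p = 8.41e-07), Sptan1 (5.67-fold), a spectrin, Slc22a5 (at least 4.11-fold), the carnitine transporter, and Pex11a (3.49-fold). Next came Apex1 (3.47-fold), a DNA repair endonuclease, Ube2g2 (3.41-fold), Tnk2 (3.17-fold), Psat1 (3.17-fold), an enzyme of serine synthesis, and Cyp4a1 (2.73-fold). Of the falls the largest were Bhlhe40 (2.90-fold), a circadian repressor, Prkd3 (2.52-fold), Hsd3b5 (2.42-fold) and Fmo1 (2.41-fold). Next came Nat1 (2.33-fold), Pklr (2.27-fold), Rbm39 (2.26-fold), Tsc22d1 (2.25-fold) and Nr1h3 (2.05-fold), the liver X receptor alpha. For these 18 genes (n = 3 against 10) standard errors of the log2 changes were at most 0.45 and adjusted p at most 0.00687. Ddit3, otherwise among the largest rises, lost its call without VPA 4 h replicate 2 (adjusted p = 0.384), and Kctd13 was called in opposite directions by 2 probe sets.

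Of the cell cycle and DNA replication list 7 of 13 rose (8 by list alone, adjusted p = 0.000226, adjusted p = 0.125 with an estimated correlation). Among them were Ccnd3 (2.14-fold), Pcna (2.15-fold), Ccnd1 (2.23-fold) and Mcm7 (1.68-fold). Of acute phase proteins 7 of 24 fell and 2 rose (9 and 3 by list alone, adjusted p = 0.00103, adjusted p = 0.185 with an estimated correlation). The rises included Socs3 (at least 3.25-fold), an inhibitor of cytokine signalling rather than a secreted protein. Of the list of gluconeogenesis, amino acid catabolism and urea cycle 5 of 30 fell and 2 rose (9 and 3 by list alone, adjusted p = 0.00348, adjusted p = 0.207 with an estimated correlation). The falls included Fah (1.43-fold). Of genes of glutathione, NRF2 targets and conjugation 4 of 25 fell and 1 rose (adjusted p = 0.0439, adjusted p = 0.304 with an estimated correlation). Of the peroxisomal list 4 of 14 members rose, Ech1 (2.00-fold) and Acaa1b (2.11-fold) among them, and 2 fell (5 and 4 by list alone). Of the mitochondrial list 5 of 20 rose, Cpt2 (1.90-fold) and Acot2 (at least 2.73-fold) among them, and neither list passed its test (adjusted p = 0.982 and 0.525).

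In all 616 of 4269 probe sets were higher and 290 lower (limma, n = 3 against 10, not time-matched), and 830 were called with scan day as a block. Median centring moved the median of all log2 changes by -0.14 and gave 393 higher and 574 lower, and quantile normalization gave 388 and 362. The count was 515 without VPA 4 h replicate 2, 559 in a fit of all 18 groups and 1388 against the mean of all 6 vehicle groups.

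At 24 h the largest VPA rises were Acot1 (at least 109-fold, adjusted p = 4.57e-20, 9 of 10 vehicle arrays at the floor), Acot2 (at least 31.7-fold), Acaa1b (10.9-fold), Pdk4 (10.0-fold) and Slc22a5 (at least 9.39-fold). Next came Pex11a (8.68-fold), Ech1 (8.62-fold), Aldh1a1 (7.06-fold), Sptan1 (6.46-fold) and Cyp2b2 (6.17-fold). Leading the falls were Cyp7a1 (at least 19.0-fold, adjusted p = 1.69e-05, 2 of 3 treated arrays at the floor), Pklr (6.24-fold), Car3 (6.14-fold), Hsd3b5 (6.03-fold) and Oat (5.75-fold), ornithine aminotransferase. Next came Stk39 (5.16-fold), Hao2 (4.87-fold), Bhlhe40 (4.19-fold), Egr1 (4.05-fold) and Crem (3.81-fold). Standard errors of the log2 changes were at most 0.63 and adjusted p at most 0.00534 for these genes (n = 3 against 10).

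Of mitochondrial beta-oxidation genes 14 of 20 rose and 1 fell (adjusted p = 2.65e-07 and 0.00695 with an estimated correlation). The rises included Cpt2 (3.39-fold), Eci1 (5.40-fold) and Hadhb (2.92-fold). Of peroxisomal genes 8 of 14 rose and 1 fell (8 and 3 by list alone, adjusted p = 0.000681, adjusted p = 0.104 with an estimated correlation). The rises included Ehhadh (4.94-fold). Of male-predominant liver genes 9 of 11 fell (10 by list alone, adjusted p = 1.44e-06, adjusted p = 0.0865 with an estimated correlation). Among them were Cyp2c11 (3.10-fold) and Cyp2a2 (2.23-fold). Of fatty acid synthesis genes 6 of 10 fell (adjusted p = 0.00367, adjusted p = 0.195 with an estimated correlation). Among them were Acly (3.11-fold) and Srebf1 (2.38-fold). Of cholesterol synthesis genes 7 of 15 fell (adjusted p = 0.0357, adjusted p = 0.518 with an estimated correlation). Of bile acid synthesis and transport genes 7 of 16 fell and 2 rose (9 and 2 by list alone, adjusted p = 0.00349, adjusted p = 0.163 with an estimated correlation). Lower members included Slc10a1 (2.11-fold) and Slco1a4 (3.43-fold), both uptake carriers. Of acute phase proteins 15 of 24 fell and 2 rose (16 and 2 by list alone, adjusted p = 3.56e-06, adjusted p = 0.0865 with an estimated correlation). Lower members included C9 (2.43-fold) and Cp (1.62-fold). Of the list of gluconeogenesis, amino acid catabolism and urea cycle 12 of 30 fell and 3 rose (13 and 3 by list alone, adjusted p = 0.00185, adjusted p = 0.185 with an estimated correlation). Lower members included Oat, Bhmt (2.21-fold) and Kmo (1.88-fold).

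Of heat shock proteins 8 of 12 rose (9 by list alone, adjusted p = 0.00219, adjusted p = 0.195 with an estimated correlation). Among them were Stip1 (2.52-fold) and Hspb1 (2.73-fold). Of the cell cycle list 7 of 13 rose (8 by list alone, adjusted p = 0.000976, adjusted p = 0.163 with an estimated correlation). Among them were Ccnd1 (4.25-fold), Cdk4 (2.05-fold), Stmn1 (2.90-fold) and Pcna (1.83-fold). Of proteasome subunits 14 of 26 rose (16 by list alone, adjusted p = 0.000499, adjusted p = 0.28 with an estimated correlation). Of ribosomal proteins 17 of 41 rose and 1 fell (18 and 1 by list alone, adjusted p = 0.00333, adjusted p = 0.477 with an estimated correlation). Of stellate cell, fibroblast and matrix markers 4 of 14 fell (adjusted p = 0.0125, adjusted p = 0.163 with an estimated correlation). Among them was Lox (3.26-fold). Of erythroid and blood markers 4 of 5 fell (adjusted p = 0.0195, adjusted p = 0.317 with an estimated correlation). Among them was Hbb (1.86-fold). In all 891 probe sets were higher and 667 lower (limma, not time-matched), and 1163 were called with scan day as a block. Median centring moved the median of all log2 changes by -0.10 and gave 690 higher and 934 lower.

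At 48 h, against time-matched vehicle, the largest VPA rises were Acot1 (at least 177-fold, adjusted p = 7.91e-21, 4 of 5 vehicle arrays at the floor), Acot2 (at least 43.7-fold), Acaa1b (19.4-fold), Pex11a (16.6-fold) and Fabp3 (at least 13.8-fold). Next came Pdk4 (13.1-fold), Ech1 (10.2-fold), Slc22a5 (at least 10.1-fold), Aldh1a1 (9.19-fold) and Acsm2 (at least 8.65-fold), an acyl-CoA synthetase of medium-chain acids. In the other direction the largest were Cyp7a1 (at least 19.1-fold, adjusted p = 1.14e-05, 2 of 4 treated arrays at the floor), Car3 (11.7-fold), Oat (7.26-fold), Pklr (7.09-fold) and Acly (5.77-fold), which makes cytosolic acetyl-CoA. Next came Lox (at least 5.73-fold), Fmo1 (5.67-fold), Mug1 (5.55-fold), a protease inhibitor of plasma, Chka (5.53-fold) and Cyp2c11 (5.28-fold). The 20 genes (n = 4 against 5) had standard errors of the log2 changes up to 0.64 and adjusted p of at most 6.77e-05.

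Of mitochondrial beta-oxidation genes 17 of 20 rose (adjusted p = 1.30e-09 and 0.00211 with an estimated correlation). Of peroxisomal genes 8 of 14 rose and 2 fell (adjusted p = 0.000299, adjusted p = 0.0865 with an estimated correlation). Higher members included Ehhadh (6.14-fold). Of proteasome subunits 21 of 26 rose and 2 fell (21 and 3 by list alone, adjusted p = 4.38e-09, adjusted p = 0.0895 with an estimated correlation). The rises included Psmb3 (2.40-fold) and Psmd1 (2.37-fold). Of ribosomal proteins 11 of 41 rose and 1 fell (adjusted p = 0.00673, adjusted p = 0.518 with an estimated correlation), with Rps29 (1.40-fold) the fall. Of heat shock proteins 8 of 12 rose (adjusted p = 0.000555, adjusted p = 0.163 with an estimated correlation). Among them were Hspb1 (6.58-fold) and Hspa1a (at least 4.80-fold). Of fatty acid synthesis genes 7 of 10 fell and 1 rose (adjusted p = 0.000554, adjusted p = 0.15 with an estimated correlation). Lower members included Srebf1 (4.63-fold). Of cholesterol synthesis genes 10 of 15 fell (11 by list alone, adjusted p = 0.000127, adjusted p = 0.195 with an estimated correlation). Among them were Cyp51 (4.22-fold), Nsdhl (3.42-fold) and Msmo1 (2.97-fold). Of bile acid synthesis and transport genes 11 of 16 fell and 1 rose (adjusted p = 0.00125, adjusted p = 0.118 with an estimated correlation). Lower members included Cyp7a1, Slco1a4 (4.24-fold) and Slc10a1 (2.65-fold). Of male-predominant genes 7 of 11 fell (9 by list alone, adjusted p = 7.52e-05, adjusted p = 0.148 with an estimated correlation). Among them were Cyp2c11, Igf1 (1.93-fold) and Rup2 (1.58-fold). Of acute phase proteins 16 of 24 fell and 1 rose (17 and 2 by list alone, adjusted p = 3.98e-06, adjusted p = 0.0865 with an estimated correlation). Lower members included C9 (4.37-fold) and Serpina3m (3.48-fold).

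Of stellate cell, fibroblast and matrix markers 5 of 14 fell (adjusted p = 0.00412, adjusted p = 0.118 with an estimated correlation). Among them was Col3a1 (3.77-fold). Of erythroid and blood markers 3 of 5 fell (adjusted p = 0.0134, adjusted p = 0.294 with an estimated correlation). Among them was Hbb (3.52-fold). Of leukocyte and Kupffer cell markers 5 of 17 members fell (4 by list alone), Pf4 (2.51-fold), a platelet chemokine, among them, and the list did not pass its test (adjusted p = 0.053). Atp5if1 (5.23-fold, log2 change 2.39 ± 0.18, adjusted p = 7.46e-10), the ATP synthase inhibitor, rose in an oxidative phosphorylation list that did not pass (adjusted p = 0.202), and the list of glutathione, NRF2 targets and conjugation did not pass either (adjusted p = 0.208). In all 911 of 4269 probe sets were higher and 784 lower (limma, n = 4 against 5), and 1726 were called with scan day as a block. Median centring turned the majority to 801 higher and 918 lower.

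At 168 h no probe set was called after VPA (limma, n = 4 against 5), with 326 of 4269 at an unadjusted p under 0.05 and 3 calls with only the groups compared. No list member was called over all genes, and 1 in each of 4 lists adjusted over the list alone. As lists, bile acid synthesis and transport, inducible phase I enzymes, glutathione, NRF2 targets and conjugation, male-predominant genes, acute phase proteins and ribosomal proteins tended lower (adjusted p = 0.0477, 0.0101, 0.00333, 0.0149, 0.000722 and 0.0185), the acute phase list turning upward under quantile normalization (median log2 0.07), and leukocyte and Kupffer cell markers tended higher (adjusted p = 0.000537). None kept its call, with adjusted p = 0.294, 0.177, 0.163, 0.35, 0.177, 0.575 and 0.277 with an estimated correlation.

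**Figure D4:**
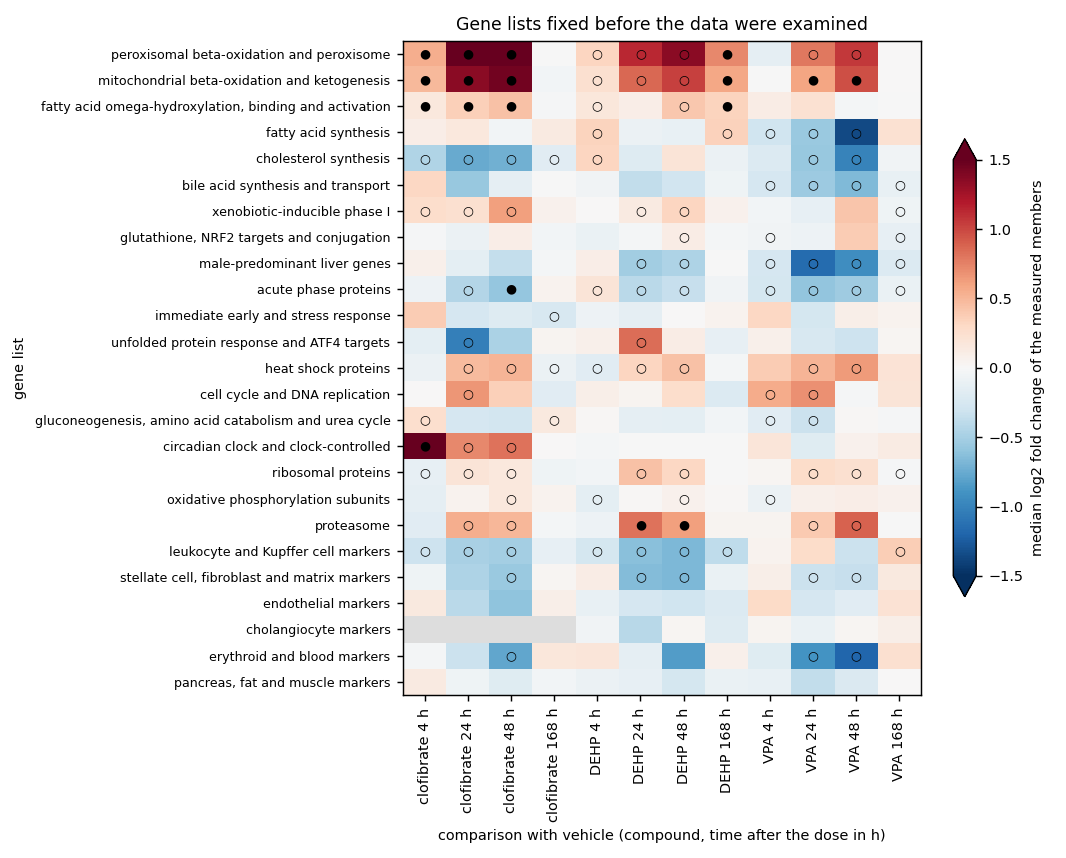
Median log2 fold change against vehicle of the measured members of each of 25 gene lists (vertical axis) in each comparison by compound and time after the dose in h (horizontal axis), coloured from -1.5 to 1.5. Filled circles mark lists called with the preset and the estimated correlation, open circles the preset alone, and grey fewer than 3 measured members. Filled circles number 18 and lie mostly in the 3 uppermost lists.

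The text gives, for each treated comparison with called probe sets and each difference of responses, the lists with 4 or more called members, those kept with an estimated correlation and all called lists of other cell types. The remaining calls of treated comparisons stand in the heat map alone. Over the 12 treated comparisons 119 of 296 list tests were called with the preset correlation and 18 with an estimated one. The lists of endothelial markers, cholangiocyte markers and markers of pancreas, fat and muscle passed in none, with lowest adjusted p values of 0.116, 0.335 and 0.0834. Where a list's median, mean and test differed in sign, in 45 of the 296 tests, the list was not called.

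The vehicle groups at 48 and 168 h were set against each other to show the change without a compound. No probe set was called in any of the 3 sets (limma, n = 5 against 5), and 114 of 3616 for clofibrate vehicle, 179 of 4092 for DEHP vehicle and 186 of 4269 for VPA vehicle had an unadjusted p under 0.05. In clofibrate vehicle the lists of immediate early and stress response (adjusted p = 0.0433, adjusted p = 0.469 with an estimated correlation) and of gluconeogenesis, amino acid catabolism and urea cycle (adjusted p = 0.0233, adjusted p = 0.445 with an estimated correlation) tended lower at 48 h. In VPA vehicle the male-predominant list tended lower at 48 h (adjusted p = 0.0129, adjusted p = 0.437 with an estimated correlation).

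The change between 48 and 168 h was tested as a difference of responses within each compound. For clofibrate the 48 h response was larger for Acaa1b by 5.37, Eci1 by 5.16 and Ehhadh by 5.07 on the log2 scale, for DEHP for Gsta3 by 2.84, and for VPA for Pex11a by 4.15 and Acaa1b by 4.10. For Cyp7a1 the difference was -4.88 or below for DEHP and -4.10 or below for VPA, and for Pklr -2.62 or below and -2.83. Acot1 was called for all 3, with no size given, as signals on both sides of the difference lay at the floor. In all 213 probe sets differed for clofibrate (107 higher at 48 h, 106 lower), 555 for DEHP (229 and 326) and 1004 for VPA (541 and 463) by limma, with 164, 486 and 1050 when scan day was a block. For clofibrate the count was 497 with the 3'/5' ratio as a covariate, 231 without the 4 arrays given to 1 decimal, 616 in a fit of all 18 groups and 750 with array weights, and for DEHP and VPA the fit of all 18 groups gave 250 and 647.

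For lists, with clofibrate the response at 48 h exceeded that at 168 h in peroxisomal genes (8 of 13, 9 and 1 by list alone), mitochondrial beta-oxidation (13 of 19, 15 by list alone) and omega-hydroxylation, binding and activation (5 of 18, 6 and 3 by list alone), with adjusted p = 2.30e-11, 6.10e-21 and 1.57e-05, and adjusted p = 1.46e-05, 1.78e-05 and 0.00248 with an estimated correlation. It was lower in acute phase proteins (7 of 23, 12 by list alone), stellate cell markers (1 of 10, 3 by list alone) and erythroid markers (2 of 5), with adjusted p = 7.98e-07, 0.0268 and 0.025, and adjusted p = 0.0138, 0.0944 and 0.352 with an estimated correlation. With DEHP it exceeded the 168 h response in proteasome subunits (16 of 26, 1 opposite, 18 and 1 by list alone), inducible phase I enzymes (6 of 15, 2 opposite), glutathione, NRF2 targets and conjugation (7 of 24, 1 opposite) and ribosomal proteins (4 of 41, 1 by list alone), with adjusted p = 5.26e-13, 0.0023, 0.00289 and 6.93e-09, and adjusted p = 0.0125, 0.12, 0.083 and 0.352 with an estimated correlation. It was lower in male-predominant genes (5 of 11, 7 and 1 by list alone), acute phase proteins (8 of 23, 8 and 1 by list alone) and stellate cell markers (6 of 14, 8 by list alone), with adjusted p = 0.00759, 0.00817 and 0.00131, and adjusted p = 0.364, 0.531 and 0.178 with an estimated correlation. With VPA it exceeded the 168 h response in peroxisomal genes (9 of 14), mitochondrial beta-oxidation (13 of 20, 14 by list alone), proteasome subunits (21 of 26, 2 opposite), inducible phase I enzymes (5 of 15, 2 opposite, 7 and 2 by list alone), glutathione, NRF2 targets and conjugation (8 of 25, 3 opposite, 10 and 3 by list alone), heat shock proteins (6 of 12) and ribosomal proteins (7 of 41, 1 opposite), with adjusted p = 7.78e-06, 7.51e-11, 1.72e-10, 0.0327, 0.0338, 0.00655 and 0.00131, and adjusted p = 0.0305, 0.000536, 0.0837, 0.352, 0.381, 0.352 and 0.531 with an estimated correlation. It was lower in fatty acid synthesis (7 of 10), cholesterol synthesis (8 of 15, 10 by list alone), bile acid synthesis and transport (5 of 16, 1 opposite, 7 and 1 by list alone), male-predominant genes (5 of 11), acute phase proteins (9 of 24, 1 opposite, 11 and 1 by list alone), leukocyte and Kupffer cell markers (2 of 17), stellate cell markers (4 of 14) and erythroid markers (3 of 5, 4 by list alone), with adjusted p = 0.000108, 0.00131, 0.0156, 0.00251, 0.000227, 0.00494, 0.0048 and 0.00722, and adjusted p = 0.118, 0.381, 0.306, 0.352, 0.197, 0.474, 0.12 and 0.352 with an estimated correlation. Over all 6 differences of responses 56 of 149 list tests were called with the preset correlation and 14 with an estimated one, and 19 of the 56, outside the stated rule, are not given.

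Clofibrate and DEHP were set side by side at 48 h, although their doses differed. The responses differed for Cyp7a1, higher with clofibrate by at least 4.44 on the log2 scale (adjusted p = 0.000222), Irf7 by at least 2.90 (adjusted p = 0.0019) and Aqp3 by at least 2.88 (adjusted p = 0.000346), and for Nqo1, lower with clofibrate (-2.26, adjusted p = 0.0461). Fabp3 was called too (adjusted p = 2.02e-11), with no size given, as signals on both sides lay at the floor. In all 50 probe sets of 4503 had the higher response with clofibrate and 43 with DEHP (limma, n = 5 per group). As a list, the unfolded protein response (4 of 17, 7 by list alone, adjusted p = 2.48e-05, adjusted p = 0.0904 with an estimated correlation) lay lower with clofibrate, and 5 more lists with fewer called members passed, 2 higher and 3 lower. The count was 34 with scan day as a block, 154 with the 3'/5' ratio as a covariate, 49 without the 4 arrays given to 1 decimal, 685 with array weights and 29 with only the groups compared. Leaving out 1 array moved it to 55 and 198 (clofibrate 48 h replicates 2 and 5), 181, 49 and 60 (clofibrate vehicle 48 h replicates 1, 4 and 5) and 47 (DEHP vehicle 48 h replicate 1).

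At 168 h the responses to DEHP were set against those to each other compound, a comparison added after the counts were seen. DEHP exceeded clofibrate for Acaa1b by 4.07, Cyp4a1 by 3.27 and Eci1 by 3.00 on the log2 scale and lay below it for Apoa4 (-2.59), and Acot1 and Acot2 were called with no size given, as signals on both sides lay at the floor. Higher with DEHP as lists were peroxisomal genes (4 of 14, 6 by list alone), mitochondrial beta-oxidation (8 of 20, 10 by list alone) and omega-hydroxylation, binding and activation (4 of 19, 7 by list alone), with adjusted p = 3.82e-15, 4.46e-19 and 1.84e-11, and adjusted p = 4.11e-06, 1.78e-05 and 1.23e-06 with an estimated correlation. Lower were leukocyte and Kupffer cell markers (0 of 19), with adjusted p = 0.00346, and adjusted p = 0.352 with an estimated correlation. Against VPA the differences were 4.02 for Acaa1b, at least 3.38 for Acot2, 3.10 for Cyp4a1 and -2.70 for Apoa4, and Acot1 was called with no size. The same lists lay higher with DEHP, peroxisomal genes (4 of 14, 5 by list alone), mitochondrial beta-oxidation (5 of 20, 10 by list alone) and omega-hydroxylation, binding and activation (4 of 19, 5 by list alone), with adjusted p = 5.28e-17, 2.68e-18 and 4.91e-12, and adjusted p = 1.23e-06, 2.65e-05 and 1.23e-06 with an estimated correlation, and leukocyte and Kupffer cell markers lower (1 of 19, 11 by list alone, adjusted p = 4.91e-12 and 0.00447 with an estimated correlation). In all 33 probe sets were higher and 2 lower against clofibrate, and 30 higher and 5 lower against VPA (limma, n = 5 per group, 4 for treated VPA).

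On the scan days that held both arms of a comparison 98.1 to 100% of the called probe sets had the sign of the whole comparison, to which the same arrays contributed.

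The 3 compounds shared much of their response at 48 h. Clofibrate and DEHP both raised 193 probe sets against 36.6 for independent lists and both lowered 277 against 98.1, with 6 called in opposite directions. Clofibrate and VPA both raised 199 against 55.2 and both lowered 248 against 92.1, with 19 opposite. DEHP and VPA both raised 348 against 104.7 and both lowered 415 against 166.8, with 44 opposite. The log2 changes correlated across probe sets with r = 0.75, 0.63 and 0.69, where genes are not independent replicates, and the vehicle groups were separate for each compound. At 4 h the correlations were 0.47 for clofibrate and DEHP, 0.35 for clofibrate and VPA and 0.20 for DEHP and VPA, and at 168 h 0.11, 0.12 and 0.12.

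Arrays of pooled RNA were compared with those of individual animals. Probe sets for Ugt2b, a glucuronosyltransferase family, read higher on pooled arrays, by 1.92 ± 1.40 (SD over 18 groups) on the log2 scale in 16 of 18 groups and by 0.70 ± 0.63 in 16 groups for a different probe set, and Gsr read 0.78 ± 0.60 higher in 17 groups. The lowest readings on pooled arrays were for Fstl1 (-0.50 ± 0.48, 14 groups), Tln1 (-0.49 ± 0.66, 13 groups) and Alkbh7 (-0.49 ± 0.48, 14 groups). The spread of log2 signals of the pooled array around the mean of its individual arrays was 0.344 on average, below the scaled spread of 1 individual array around the others (0.463), by 0.119 ± 0.078 (SD) and in 18 of 18 groups (exact sign-flip permutation test, two-sided p = 7.63e-06, the smallest it can give). Per the labels a pool holds RNA of each sample, so it averages the differences between animals that widen the spread of individual arrays, and a smaller spread is expected by design. The p treats groups as independent, although pools share scan days and their deviations correlate within a day (mean r 0.266). On average 70.7% of pooled signals (52.9 to 86.1% by group) lay within the range of the individual arrays. Within the range of all individual arrays but 1 lay 58.7% of pooled signals and 50.3% of those of the array left out, and such shares depend on the number of arrays.

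Fold changes from 1 pooled treated and 1 pooled vehicle array correlated with those of the individual arrays, across probe sets, with r = 0.854 for clofibrate, 0.858 for DEHP and 0.897 for VPA at 48 h, and 0.388, 0.603 and 0.0813 at 168 h. The pooled sign matched in 98.1, 95.6 and 97.6% of the probe sets called at 48 h and in 94.6% of those called for DEHP at 168 h. Of probe sets differing by at least 2-fold between the pooled arrays, 266 of 471 (clofibrate), 309 of 409 (DEHP) and 508 of 584 (VPA) were also called in the individual animals at 48 h. At 168 h this held for 54 of 197 with DEHP, for 0 of 161 with clofibrate and for 0 of 125 with VPA, where no probe set was called by limma and 78 and 326 had an unadjusted p under 0.05. A single pool per group allows no test of its own, and pooled arrays were scanned on 6 days that held no individual array, so pooling and scan day cannot be told apart.

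**Figure D5:**
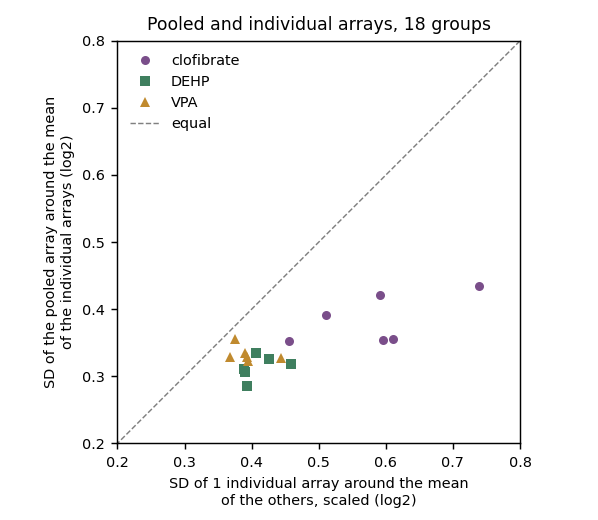
Spread (SD of log2 signal differences) of the pooled array around the mean of its individual arrays (vertical axis) against the scaled spread of 1 individual array around the mean of the others (horizontal axis), 1 point per group of 18. The dashed line marks equality, and all 18 points lie below it.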

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

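The tests of the 3'/5' ratio, of the 4 arrays given to 1 decimal, of compound pairs within the pooled arrays, of the spread over groups for linear averaging and of the DEHP responses at 168 h were chosen only after the result was seen.

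Of 36 sets of array values tested for 1 value far from the others, 3 had one, and chance gives about 1 in 20. They were the correlation with the other arrays of the group for clofibrate 48 h replicate 5 (0.950, others 0.977 to 0.983) and for clofibrate vehicle 168 h replicate 5 (0.960, others 0.979 to 0.987), and the log2 3'/5' ratio of DEHP vehicle 168 h replicate 1 (0.789, others 0.224 to 0.301).

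Responses differed between 48 and 168 h by the limma test of the difference. For clofibrate 213 probe sets did, with Acot1 (8.26), Acaa1b (5.37), Eci1 (5.16), Ehhadh (5.07), Acot2 (4.49), Mpv17l (-3.02), Dio1 (-2.92), Fmo1 (-2.84), Apoa4 (-2.83) and Hsd11b1 (-2.37 on the log2 scale). For DEHP 555 did, with Acot1 (2.84), Gsta3 (2.84), Cyp3a9 (2.79), Pdk4 (2.35), Slc3a2 (2.09), Cyp7a1 (-4.88), Fmo1 (-3.70), Car3 (-2.91), Tsc22d1 (-2.66) and Pklr (-2.62). For VPA 1004 did, with Acot1 (7.47), Acot2 (4.85), Pex11a (4.15), Acaa1b (4.10), Fabp3 (3.73), Cyp7a1 (-4.10), Car3 (-3.33), Acly (-3.07), Oat (-2.88) and Pklr (-2.83). Between clofibrate and DEHP at 48 h 93 did, with Cyp7a1 (4.44), Fabp3 (4.25), Irf7 (2.90), Aqp3 (2.88), Sult1c2a (2.30), Nqo1 (-2.26), Mpv17l (-1.86), Cyp51 (-1.60), Aspg (-1.51) and Sult2a1 (-1.46). At 168 h 35 differed between DEHP and clofibrate, with Acot1 (5.23), Acot2 (4.18), Acaa1b (4.07), Cyp4a1 (3.27), Eci1 (3.00), Apoa4 (-2.59) and Cd63 (-1.56), and 35 between DEHP and VPA, with Acot1 (5.23), Acaa1b (4.02), Acot2 (3.38), Cyp4a1 (3.10), Aldh1a1 (2.56) and Apoa4 (-2.70). Signals at the floor of 150 lay on both sides of the differences for Acot1 (all 5), Acot2 (clofibrate 48 minus 168 h and DEHP minus clofibrate), Fabp3 (VPA and clofibrate minus DEHP), Sult1c2a and Mpv17l (clofibrate minus DEHP), and those values measure no size. The values are lower bounds for Mpv17l (clofibrate), Cyp7a1 (all 3), Pklr (DEHP), Acot2 (VPA and DEHP minus VPA), Irf7 and Aqp3.

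In 100 splits of the same arrays into groups of the same sizes, drawn with a fixed seed, the number with a count at least as large as the real one, the real one included, was 1 for DEHP at 4 h (118, highest other 54), 24 h (1334, 238), 48 h (1385, 376) and 168 h (148, 41), for VPA at 4 h (906, 128), 24 h (1558, 92) and 48 h (1695, 1221), and for the 48 minus 168 h differences of DEHP (555, 67) and VPA (1004, 2). For clofibrate it was 3 at 4 h (124, 717), 2 at 24 h (488, 738) and 3 at 48 h (722, 1095). It was 2 for clofibrate 48 minus 168 h (213, 235) and 3 for DEHP minus VPA at 168 h (35, 54). It was 6 for clofibrate minus DEHP at 48 h (93, 1800) and 8 for DEHP minus clofibrate at 168 h (35, 1982). Where other splits gave more, chance stays open. The number was 100 for clofibrate and VPA at 168 h (0, highest other 2). It was 100 for the vehicles of clofibrate, DEHP and VPA (0, highest other 0, 2 and 3). For clofibrate at 4, 24 and 48 h the splits with most calls part arrays by 3'/5' ratio, a structure of the samples. Of the others 0, 0 and 1 had a larger ratio contrast. With the ratio as covariate the counts were 204, 942 and 1046. For the 48 minus 168 h difference of clofibrate 69 other splits had a larger ratio contrast than the one with 235 calls.

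Clofibrate changes at 48 h were weighed against RNA quality, as treated arrays had the lower 3'/5' ratio. With the ratio as a covariate 96.8% of called probe sets kept their call and direction. Without the 4 arrays of highest ratio log2 changes had a slope of 0.962 on the original ones. The former argues against the ratio as the whole cause, the latter only against those arrays, and a part stays open.

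The changes at 4 h were weighed against time of day or handling shared by the 3 studies, as no vehicle animals were killed then. Shared handling needs similar changes with every compound, and the lower slope of the other compounds' log2 changes over the called probe sets was 0.395 for clofibrate, 0.390 for DEHP and 0.223 for VPA. These argue against it as the whole cause for the called probe sets as a set. For clofibrate calls the slope in DEHP was 0.559, with 88.2% of signs shared with DEHP and 82.6% with VPA, and for DEHP calls the slope in clofibrate was 0.929 with 88.6% of signs shared. For those genes, and for genes such as Pdk4 that rose with all 3 compounds, a shared effect of the compounds and of handling stays open.

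The distance of pooled arrays from their individual arrays was weighed against averaging on the linear scale and scan batch. Against the log2 of the arithmetic mean the median spread was 97.6% of that against the mean of log2 signals, over the 95% written beforehand as the bound (89.3 to 100.1% by group, mean 96.7%, standard error 0.69, 14 of 18 groups over 95%). This argues against averaging as the whole cause, and a part in single groups stays open. The other outcome written, a spread at or below that of individual arrays, was met before the correction (0.332 against 0.416) and decides nothing. Deviations of pooled arrays scanned on 1 day correlated across probe sets with a mean r of 0.266 (31 pairs), and those of different days with 0.0904 (122 pairs). All same-day pairs were of 1 compound, and pairs of 1 compound scanned on different days gave 0.240 (14 pairs), so that scan day and compound cannot be told apart. No biological explanation was tested.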

How the results depend on the processing

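The 3'/5' ratio as a covariate, array weights, the fit without the 4 arrays given to 1 decimal and both 168 h differences between compounds were chosen after seeing the data. Of 762 named gene results 603 kept their call whichever single array was left out. Of 119 calls among 296 list tests 101 were lost with an estimated correlation. Every count called under the main settings stayed above 0. For the counts below that moved by over 1.5 times the cause was not tested, except where fewer probe sets or arrays were used.

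With 1 probe set per gene, fewer were tested: clofibrate 4 h 78, 24 h 317, 48 h 433, DEHP 4 h 73, 24 h 763, 48 h 795, 168 h 72, VPA 4 h 574, 24 h 908, 48 h 986, and 48 minus 168 h 135, 298 and 585. With a fold of at least 1.5: DEHP 24 h 801, 48 h 806, VPA 4 h 550, 24 h 978. With all 18 groups in the fit: clofibrate 4 h 295, 24 h 873, 48 h 1232, its vehicles 5, VPA 4 h 559, and 48 minus 168 h 616, 250 and 647. With array weights: clofibrate 4 h 646, 24 h 911, 48 h 1379, 168 h 1, its vehicles 3, its 48 minus 168 h 750, clofibrate minus DEHP 685. With the 3'/5' ratio as covariate: clofibrate 4 h 204, 24 h 942, its 48 minus 168 h 497, clofibrate minus DEHP 154. With only the groups compared: clofibrate 48 h 479, VPA 168 h 3, clofibrate minus DEHP 29. With the scan-day block: DEHP 4 h 59, clofibrate minus DEHP 34. Without the 4 arrays given to 1 decimal: clofibrate minus DEHP 49. With the floor of 300: clofibrate and VPA vehicles 1 each. With no filter: DEHP vehicles 1. Against the 168 h vehicle group alone: clofibrate 4 h 79, DEHP 4 h 72. Against the mean of all 6 vehicle groups: clofibrate 4 h 735, 24 h 2284, DEHP 4 h 386, VPA 4 h 1388, and Kdr at DEHP 24 h turned to log2 0.15. Under quantile normalization the result for the list of acute phase proteins, VPA 168 h, turned to a median log2 of 0.0693.

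Leaving out 1 array moved the counts over 78 to 140 (clofibrate 4 h), 327 to 484 (24 h), 529 to 852 (48 h), 0 to 1 (168 h), 54 to 149 (DEHP 4 h), 912 to 1331 (24 h), 1159 to 1399 (48 h), 101 to 152 (168 h), 515 to 929 (VPA 4 h), 1140 to 1609 (24 h), 1513 to 1666 (48 h), 170 to 293, 436 to 611 and 878 to 1075 (48 minus 168 h), 47 to 198 (clofibrate minus DEHP 48 h) and 28 to 40 for both 168 h differences.

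Same-numbered arrays shared only a number, with median correlations of their deviations from -0.214 to 0.0989, and not every array correlated best with its own number. The replicate block moved no count by over 1.5 times (clofibrate 48 h 661, DEHP 48 h 1329, VPA 48 h 1613). Chip lot was not run, as the scanner field held no lot. Lists have no value for a fold threshold or for 1 probe set per gene, as they use neither, and the early vehicle alternatives were not applied to them. Signal over background limits small changes, as 33.2 to 45.9% of probe sets per array reached 500.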
